A study of Homo sapiens with 8 samples.

How the data were processed

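Total RNA of MDA-MB-231 cells was extracted with a column kit and made into libraries with a strand-specific kit, per the labels' protocols. The deposited table holds estimated counts per gene symbol for 8 samples, not normalised, as its header and values show. Values were called whole within a tolerance of 0.01, and 84.3% were. The aligner, the counting tool, its use of strand, and any filter are not given in the sources used here. The genome build was GRCh38, per the submitters' processing notes. The smallest row sum over the 8 samples was 10.0, so rows of fewer counts were not analysed here. Reads of overlapping genes, antisense genes and close paralogs may be shared between rows, since the counting rule is not given. In 34 lists of genes, older symbols were matched by alias through a RefSeq table (GRCh38.p14), in which 15688 of 17022 named rows were found.

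The table has 17046 rows, and in 24 of them the symbol was a date, as spreadsheets write when they misread a name. Those rows name no gene and were left out of library sizes and tests. They held 0.041% and 0.046% of the counts in the scrambled libraries and 0.097% and 0.051% in the knockdown libraries. Estimated counts were rounded to whole numbers before any test.

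The labels give 4 title stems, each with the endings L3 and L4, whose meaning they do not state. A rule set before the data were examined treated samples that share a stem as 1 library if chi-square per degree of freedom of their counts was under 1.2 and pairs with different stems had at least 1.5 times that value. Over all rows with at least 10 counts, as the rule was written, pairs that share a stem had 1.88 to 2.75, so the limit was missed. Estimated counts need not follow counting noise, so the values were also taken over the 13380 rows whole in all 8 samples, a restriction chosen after the data were seen. There they had 1.23 to 1.27, still above the limit. Pairs with different stems had 4.31 to 4.56 in the knockdown and 23.7 to 24.1 in the scrambled group over whole rows. By the letter of the rule the 8 samples would have entered as 8 libraries. The rule was departed from and the samples were summed by stem, a decision made after these values were seen. Mean chi-square lay between 1.13 and 1.29 in every count range up to 10000, and between 1.43 and 1.98 above it. Samples this close, taken as separate replicates, would have lowered the estimated spread. The biological coefficient of variation was 3.09% between samples sharing a stem and 14% in the fit of 4 libraries. The fit of 8 samples, which the rule called for, is given beside the count of changed genes.

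Groups were compared with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood F test, 2 residual degrees of freedom before moderation), UBR7 knockdown against scrambled, with no covariate. P-values were adjusted by Benjamini-Hochberg over the 16076 genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The gene lists were fixed before the data were examined, and 33 of them had at least 5 tested members; none of the mitochondrially encoded genes of the remaining list was analysed here. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), adjusted over the 33 lists. With an estimated correlation, none of the 22 calls held. That form of camera uses the 2 residual degrees of freedom, so it had little power to pass any list here. Its estimated correlations for the collagens and the mesenchymal markers, -0.014 and -0.02, lay below the preset 0.01, so correlation does not explain their losses. They lay above it for other lists, such as the histones (0.444), G2/M (0.238), TGF-beta target (0.149) and S phase (0.113) genes. For such lists correlation may account for part of the loss. Counts of members are given over all genes and adjusted over the list alone.

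Genes were named by a rule set before the data were examined. It took a fixed set that included UBR7, EZH2, CDH4, TGFB1 and TGFB2. It added the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM, a protein-coding annotation where given, and all knockdown libraries on one side of all scrambled libraries. It added up to 4 members with the smallest adjusted p of each list that passed or that bore on TGF-beta, matrix, mesenchymal transition or PRC2, and the 3 most abundant members of lists that did not pass. Not all of these are printed, and some are not reported here. ZBED6CL, USP44, USP18, CSF2, KDR, BMP4, FST, PHLDA3, DDIT3, ITPK1, MYH11, DES, ACTG2 and ACTA2 lie outside the rule and were chosen after their values were seen. COL1A1, DCN and LUM were fixed with the test for stromal cells. XIST and Y-linked genes are not named.

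Alternatives fixed before the data were examined were median-of-ratios and upper-quartile factors, library size alone, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 2 libraries, a block for the replicate number, 8 samples, L3 or L4 samples alone, each library left out in turn, a test against 1.5-fold, an estimated correlation and fry. Camera compares a list with the other genes, while fry tests the list against no change, so its p-values answer a different question. With 1 library left out, the spread is estimated from the remaining pair, so a call lost or gained there need not reflect a changed fold change. In counts of genes or list members, rose and fell mean calls past the threshold, also in these fits. Added after seeing the data were an offset for GC content (a lowess curve per library, span 0.3), the 12 abundant non-coding rows left out, the 8 samples for lists and the date rows kept. GC content came from transcripts of GENCODE 29 and covered 90.4% of named rows.

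The test was tried on simulated counts with the means and library sizes of the 4 libraries and 200 of 16076 genes changed. The changed genes were drawn only from genes with a mean of at least 1 CPM. It recovered 93% of the genes changed 2-fold and 99% of those changed 4-fold, with 21 false calls among 15876 unchanged genes. Both groups were given the same spread per gene, while the real SD ratio of scrambled to knockdown libraries was 2.32. These shares therefore need not hold for the real data, and they do not cover genes of lower counts. With GC trends added, 74.5% of genes changed 2-fold were recovered without and 88.5% with the correction, with 8 and 18 false calls. The trends added differed only within groups. These false calls therefore say nothing about the GC trend between knockdown and scrambled libraries in the real data. Among genes with a mean under 0.3 CPM, 24 of 2419 were called and the median SE of a log2 fold change was 0.48, against 0.15 at 5 to 20 CPM.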

Results

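The RNA sequencing compared MDA-MB-231 cells with stable short hairpin RNA against UBR7 with the same cells carrying a scrambled control. MDA-MB-231 is a human triple-negative breast cancer cell line with mesenchymal features, and UBR7 is an E3 ubiquitin ligase of the N-recognin (UBR) family that acts on histone H2B. The title of the series places UBR7 together with EZH2, the methyltransferase of Polycomb repressive complex 2 (PRC2), upstream of TGF-beta signalling and of the extracellular matrix. The comparison of knockdown with scrambled cells therefore asked which genes of these processes differed when UBR7 was lowered. Each group held 4 samples, and samples whose titles shared a stem were summed, which left 2 libraries per group. Their counts differed by more than the limit set before the data were examined for taking them as 1 library (chi-square per degree of freedom 1.88 to 2.75, and 1.23 to 1.27 over whole-valued rows; limit 1.2). The sum was nevertheless used, and the count from 8 separate samples is given beside the main one. Total counts per sample ran from 54010913 to 78063294. They summed to 153624477 and 109529606 in scrambled libraries 1 and 2 and to 122597075 and 126626608 in knockdown libraries 1 and 2. Nuclear ribosomal RNA took 55.0% and 45.6% of the counts in the scrambled libraries and 25.6% and 57.3% in the knockdown libraries. All 12 rows of abundant non-coding RNA together took 76.4% to 81.4% of the counts in the scrambled samples, 57.4% and 58.4% in the samples of knockdown library 1, and 77.8% and 78.03% in those of knockdown library 2. CPM values are normalised counts relative to all counts of a library, ribosomal RNA included. Nothing in the labels says that the libraries came from separate cultures, or whether both knockdown libraries carry the same hairpin, so p-values measure the spread between these libraries, which may be technical or, in the knockdown, lie between hairpins.

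UBR7 itself was lower in every knockdown sample. The gene lies on the forward strand of chromosome 14, and the deposited table gives its span as 93207292 to 93227035 (GRCh38), inside the annotated protein-coding gene. The 4 scrambled samples had 9.77, 11.07, 9.21 and 8.08 normalised CPM, from 540, 614, 459 and 407 counts. The 4 knockdown samples had 3.19, 3.12, 3.25 and 2.63 CPM, from 332, 327, 182 and 148 counts. By library, UBR7 stood at 9.53 ± 1.30 CPM in scrambled cells (SD, n = 2) and at 3.05 ± 0.15 CPM in knockdown cells (SD, n = 2). This was 3.13-fold lower, a log2 fold change of -1.64 ± 0.16 (SE), with an adjusted p of 0.00522 in edgeR's quasi-likelihood test.

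**Figure D1:**
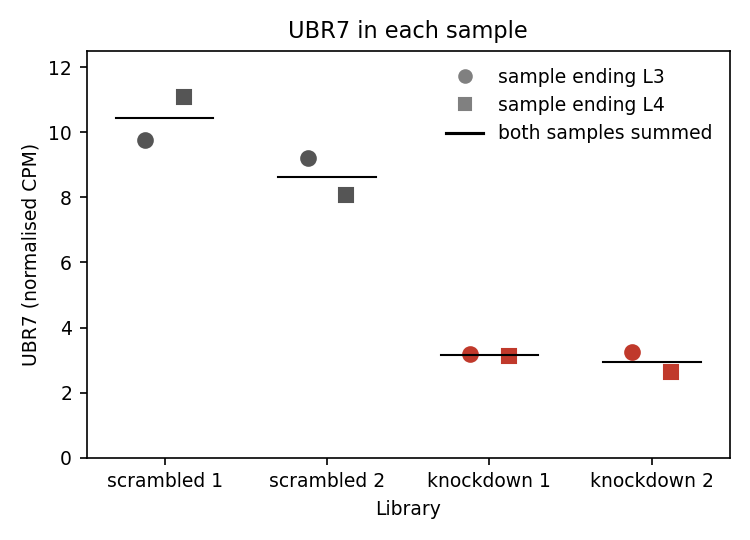
Normalised UBR7 CPM (vertical axis, linear from 0) in the 8 samples, arranged by library (horizontal axis). Circles and squares are the samples whose titles end in L3 and L4, and each black line is the value of both samples summed; the scrambled samples lie between 8.08 and 11.07 CPM and the knockdown samples between 2.63 and 3.25 CPM.

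Genes changed in both directions with knockdown of UBR7. Of 16076 genes tested, 617 changed at an adjusted p under 0.05, and 207 of these rose and 410 fell. Changes of at least 2-fold numbered 327, with 84 rises and 243 falls. With the 8 samples entered as 8 libraries, 4640 genes changed, 2184 up and 2456 down, and among them were all 606 of the 617 genes that this fit tested. The count was 223 (58 up, 165 down) without knockdown library 1 and 260 (57 up, 203 down) without knockdown library 2. It was 5986 (2976 up, 3010 down) without scrambled library 1 and 3297 (1583 up, 1714 down) without scrambled library 2, so the excess of falls was small in these fits. At least 2-fold, these fits gave 349 rises and 557 falls and 208 rises and 368 falls. Scaling by library size alone left 11 genes, 6 up and 5 down, and moved the median log2 fold change of all genes to 0.66, and 14 of the 617 genes changed sign; all directions here are relative to the other genes.

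The largest rises among genes of at least 5 CPM included cell cycle genes. SLCO4A1, an organic anion transporter, went from 2.58 ± 0.06 to 8.18 ± 0.01 CPM (SD, n = 2 each; 3.17-fold, adjusted p = 0.00338). EREG, the EGF receptor ligand epiregulin, rose 2.83-fold, and ENPP4, an ectonucleotide pyrophosphatase family member, rose 2.72-fold. SKP2, the F-box protein that targets the inhibitor p27 for degradation, rose 2.70-fold from 6.79 ± 0.40 to 18.3 ± 1.07 CPM. BIRC3, an inhibitor of apoptosis, rose 2.61-fold from 39.4 ± 8.15 to 102.8 ± 7.80 CPM. CCNE2, the cyclin E2 gene, RFC3, a subunit of the clamp loader of DNA replication, and MYBL2, a transcription factor of cycling cells, rose 2.46-, 2.21- and 2.18-fold. PLXNA1, a semaphorin receptor, FAM105A (now OTULINL), SNX16, a sorting nexin, and CD83, an immune cell surface protein, completed the 12 largest rises with 2.35-, 2.29-, 2.28- and 2.18-fold changes. Adjusted p-values of the 12 genes lay between 0.00338 and 0.0406. CD83 did not pass without knockdown library 2 (adjusted p = 0.0547; range over 18 alternatives 3.11e-06 to 0.659).

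The largest falls exceeded the largest rises in size. KIAA1199 (now CEMIP), which takes part in hyaluronan breakdown, fell 6.88-fold from 66.3 ± 5.37 to 9.64 ± 0.67 CPM (SD, n = 2 each; adjusted p = 0.00160). IL6, a pro-inflammatory cytokine, fell 4.86-fold from 51.5 ± 2.41 to 10.6 ± 0.58 CPM. The complement component C3 fell 3.37-fold from 169.3 ± 0.31 to 50.2 ± 1.11 CPM. TRIM29, a tripartite motif protein, fell 4.73-fold, CLIC3, a chloride intracellular channel protein, 4.02-fold, CPA4, a carboxypeptidase, 3.72-fold, and GPRC5B, an orphan receptor, 3.25-fold. The pregnancy-specific glycoproteins PSG5 and PSG4 fell 4.52- and 4.34-fold, and the annexins ANXA8L1 and ANXA8 fell 4.33- and 3.90-fold. These paralogs are close copies, so the counts of each member are uncertain. LRRC61 fell 3.14-fold, but it overlaps ZBED6CL, which fell 3.53-fold, and their reads may not be separable. Among the other genes named in this paragraph or as the largest rises, SKP2, CCNE2, KIAA1199, ANXA8 and GPRC5B overlap another row of the table. Adjusted p-values of the 12 falls lay between 0.00160 and 0.0274.

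**Figure D2:**
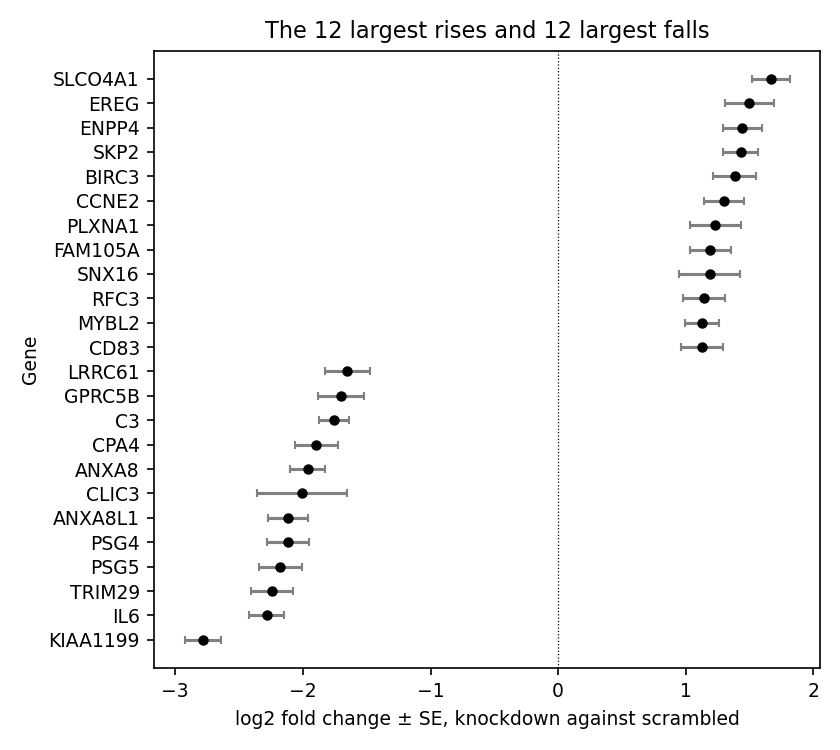
Log2 fold change of knockdown against scrambled cells (horizontal axis) with its standard error (bars) for the 12 largest rises and 12 largest falls (vertical axis). The rises end at 1.67 for SLCO4A1 and the falls at -2.78 for KIAA1199.

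TGF-beta target genes were lower in the knockdown as a group. Of 28 target genes tested, 6 fell, none rose and 22 did not pass (9 fell adjusted over the list alone), with a median log2 fold change of -0.34. By sign, 24 log2 fold changes were negative and 4 positive, and the upper quartile was -0.06, so part of the list hardly moved. NEDD9, a scaffold protein of focal adhesions, fell 3.07-fold from 29.7 ± 0.77 to 9.66 ± 0.19 CPM (SD, n = 2 each; adjusted p = 0.00235). TGFBI, a secreted matrix protein induced by TGF-beta, fell 2.24-fold (adjusted p = 0.00938). The smooth muscle gene CNN1 also fell, but from a level of 0.54 ± 0.11 CPM. Outside the lists, further smooth muscle genes, of a cell type the cultures were not labelled to hold, fell as well: MYH11 7.68-fold from 2.725 ± 0.59 CPM, DES 23.3-fold from 0.95 ± 0.02 CPM and ACTG2 13.4-fold from 0.49 ± 0.08 CPM (adjusted p = 0.00522, 0.0106 and 0.0114). These falls passed without each of the 4 libraries in turn, and over 18, 17 and 17 alternatives library size alone ended the calls of MYH11 and ACTG2, and none ended that of DES (ranges of adjusted p 7.32e-19 to 0.659 for MYH11, 7.12e-18 to 0.0206 for DES and 8.37e-09 to 0.590 for ACTG2). ACTA2, a smooth muscle gene on the list, did not pass (log2 fold change -0.38 ± 0.205 SE, adjusted p = 0.347). The list passed camera's test with its preset correlation (adjusted p = 4.90e-05). It did not pass with an estimated correlation (adjusted p = 0.316 with an estimated correlation, lowest of 13 alternatives 6.16e-06). Nor did the list pass with fry (adjusted p = 0.0547). Without knockdown library 1 or 2, 3 members fell in each case, and 13 and 9 fell without scrambled libraries 1 and 2.

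The TGF-beta ligands, receptors and SMADs did not move as a group. Of 22 tested, ACVR2B, an activin receptor, rose 1.73-fold. INHBA, a subunit of activin A, and LTBP3, a latent TGF-beta binding protein, fell 2.64- and 2.74-fold, and 19 did not pass (2 rose and 6 fell adjusted over the list alone). The list's camera adjusted p was 0.301. ACVR2B did not pass without knockdown library 1 or 2 (adjusted p = 0.254 and 0.237; lowest of 18 alternatives 5.74e-05, highest 0.659). Without scrambled libraries 1 and 2, 6 and 3 members rose and 8 and 5 fell. TGFB1 stood at 16.5 ± 1.37 CPM in scrambled and 10.3 ± 2.43 CPM in knockdown cells (SD, n = 2 each; log2 fold change -0.68 ± 0.18 SE, adjusted p = 0.0869). TGFB2 stood at 98.1 ± 25.5 and 60.4 ± 5.15 CPM (-0.70 ± 0.19, adjusted p = 0.0850). Both ligands were lower in each knockdown library than in each scrambled one, and neither passed in the main fit. In edgeR with the GC correction the adjusted p was 0.0566 for TGFB1 and 0.00063 for TGFB2. TGFB2 passed without scrambled library 1 (adjusted p = 0.00508) and without scrambled library 2 (adjusted p = 0.000468). The ligands passed in 3 and 6 of 18 alternatives, with adjusted p-values from 0.00253 to 0.920 for TGFB1 and from 0.000468 to 0.975 for TGFB2. THBS1 and SMAD3, of high CPM in the list, had 834.6 ± 69.7 and 51.7 ± 1.09 CPM in scrambled cells. In knockdown cells they had 628.8 ± 3.28 and 60.2 ± 0.45 CPM, with adjusted p-values of 0.111 and 0.351.

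Extracellular matrix genes were lower in the knockdown. Of 28 collagen genes tested, 9 fell, 1 rose and 18 did not pass (14 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.43. COL8A1, a short-chain collagen, fell 2.75-fold from 106.1 ± 5.87 to 38.7 ± 2.13 CPM (SD, n = 2 each; adjusted p = 0.00326). The fibrillar collagen COL1A2 and the fibril-associated COL16A1 and COL9A2 fell 3.03-, 3.03- and 2.66-fold, each from 6.44 CPM or less. COL6A3, a chain of the beaded-filament collagen VI, rose 1.68-fold from 5.36 ± 0.07 to 9.03 ± 0.06 CPM (adjusted p = 0.0292). Of 48 matrix glycoproteins and proteoglycans, 8 fell, none rose and 40 did not pass (17 fell and 1 rose adjusted over the list alone). FN1, fibronectin, fell 3.08-fold from 83.0 ± 2.83 to 26.9 ± 0.01 CPM (adjusted p = 0.00181). EFEMP1, a fibulin, and CSPG4, a membrane proteoglycan, fell 1.90- and 1.84-fold. FN1 overlaps another row of the table, as do LTBP3, ACVR2B and THBS1 among the TGF-beta genes. Both lists had a camera adjusted p of 3.99e-06 (adjusted p = 0.316 with an estimated correlation for both). The lowest of 13 alternatives was 9.34e-08 for the collagens and 1.56e-07 for the glycoproteins.

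Leaving out a knockdown library changed the number of matrix genes called more than their fold changes. Without knockdown libraries 1 and 2 the median log2 fold change was -0.45 and -0.44 for the collagens. For the glycoproteins it was -0.49 and -0.45, against -0.47 in the main fit. Without knockdown library 1, 6 collagens and 3 glycoproteins fell, and without knockdown library 2, 7 and 4 fell. Without scrambled library 1, 16 and 23 fell and 2 and 2 rose, and without scrambled library 2, 15 and 14 fell and 1 and 4 rose. The call of COL6A3 did not hold without knockdown library 1 or 2, though its log2 fold change stayed at 0.76 and 0.74, against 0.75. Its adjusted p ranged from 1.64e-05 to 0.659 over 18 alternatives. Markers of stromal fibroblasts, a cell type the cultures were not labelled to hold, moved the same way. Of 13 tested, COL3A1, C1S, PI16 and DCN fell, COL6A3 rose and 8 did not pass (8 fell and 1 rose adjusted over the list alone). COL1A1, COL3A1, COL6A3, DCN and LUM are also on the matrix lists above, so the marker list is not independent of them. The marker list had a camera adjusted p of 4.32e-06 (adjusted p = 0.316 with an estimated correlation; lowest of 13 alternatives 4.00e-10). Without knockdown libraries 1 and 2, 1 and 2 markers fell, and without scrambled libraries 1 and 2, 8 and 6 fell and 1 rose in each case. In scrambled cells COL1A1 and COL3A1, abundant transcripts of fibroblasts, stood at 5.93 and 5.65 CPM, and DCN and LUM at 1.19 and 1.13 CPM.

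Lists of enzymes that build, crosslink or cut the matrix also tended downward, though most members did not pass. Of 19 collagen-processing genes, the lysyl oxidases LOXL4 and LOX, the procollagen protease BMP1 and the collagen chaperone SERPINH1 fell by 2.02-, 2.19-, 2.04- and 1.61-fold, and 15 did not pass (5 fell adjusted over the list alone). Of 33 matrix proteases and inhibitors, 5 fell, 1 rose and 27 did not pass (9 fell and 1 rose adjusted over the list alone). The interstitial collagenase MMP1 fell 3.13-fold, the protease ADAMTS9 2.46-fold and the inhibitor TIMP3 1.999-fold from 74.7 ± 4.80 to 37.4 ± 0.53 CPM (SD, n = 2 each). The membrane-type protease MMP16 rose 2.24-fold. LOX and ADAMTS9 overlap another row of the table. Of 18 integrins, ITGB3 and ITGB8 fell 1.86- and 2.52-fold and 16 did not pass (2 fell adjusted over the list alone). Camera adjusted p-values were 0.00292, 0.00208 and 0.0392 for the enzymes, the proteases and the integrins (adjusted p = 0.357, 0.319 and 0.316 with an estimated correlation). With fry the adjusted p-values were 0.0935, 0.0547 and 0.0685, so none passed. These lists passed in 10, 9 and 5 of 13 alternatives, with lowest values of 0.000631, 0.000434 and 0.00720. Without knockdown library 1 no enzyme, 2 proteases and no integrin fell and none rose, and without knockdown library 2, 2, 3 and no members fell and 1 protease rose. Without scrambled library 1 the falls were 11, 13 and 6 and the rises 0, 3 and 3. Without scrambled library 2 the falls were 6, 8 and 6 and the rises 1, 3 and 1.

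Mesenchymal and epithelial markers both tended downward. Of 16 mesenchymal markers tested, 7 fell, none rose and 9 did not pass (9 fell adjusted over the list alone), with a median log2 fold change of -0.86. Besides FN1 and LOX, the mesenchymal cadherin CDH11 fell 2.496-fold from 22.1 ± 1.78 to 8.85 ± 0.01 CPM (SD, n = 2 each; adjusted p = 0.00572). The calcium-binding protein S100A4 fell 1.80-fold (adjusted p = 0.0241). Of 28 epithelial markers, 6 fell, none rose and 22 did not pass (10 fell and 1 rose adjusted over the list alone). SPINT1, a membrane protease inhibitor, fell 4.02-fold from 6.71 ± 1.38 CPM, and the keratins KRT19, KRT7 and KRT8 fell 2.04-, 2.13- and 1.62-fold. KRT8 overlaps KRT18, and S100A4 overlaps S100A5, so their counts are less certain. Camera's adjusted p was 1.52e-06 for the mesenchymal and 0.0159 for the epithelial list (adjusted p = 0.316 with an estimated correlation for both). The mesenchymal list passed in 12 of 13 alternatives (lowest 1.69e-07) and the epithelial list in 7 of 13 (lowest 0.000498). Without knockdown libraries 1 and 2, 2 and 3 mesenchymal and 2 and 3 epithelial markers fell. Without scrambled libraries 1 and 2, 10 and 7 mesenchymal and 12 and 11 epithelial markers fell, while 1 and 0 mesenchymal and 3 and 1 epithelial markers rose. Of 8 tested cadherins CDH11 fell and 7 did not pass (2 fell adjusted over the list alone). The cadherin list had a camera adjusted p of 0.0425 and passed in 6 of 12 alternatives (adjusted p = 0.316 with an estimated correlation; lowest 0.00168). Among the cadherins 3 fell without scrambled library 1, and 1 fell and 1 rose without scrambled library 2. CDH4, R-cadherin, had 12.7 ± 1.91 CPM in scrambled and 15.1 ± 0.19 CPM in knockdown cells (log2 fold change 0.25 ± 0.15 SE, adjusted p = 0.399). CDH4 passed without scrambled library 2 (adjusted p = 0.0136) and with the GC correction (adjusted p = 0.0137; range over 18 alternatives 0.0136 to 0.9998).

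**Figure D3:**
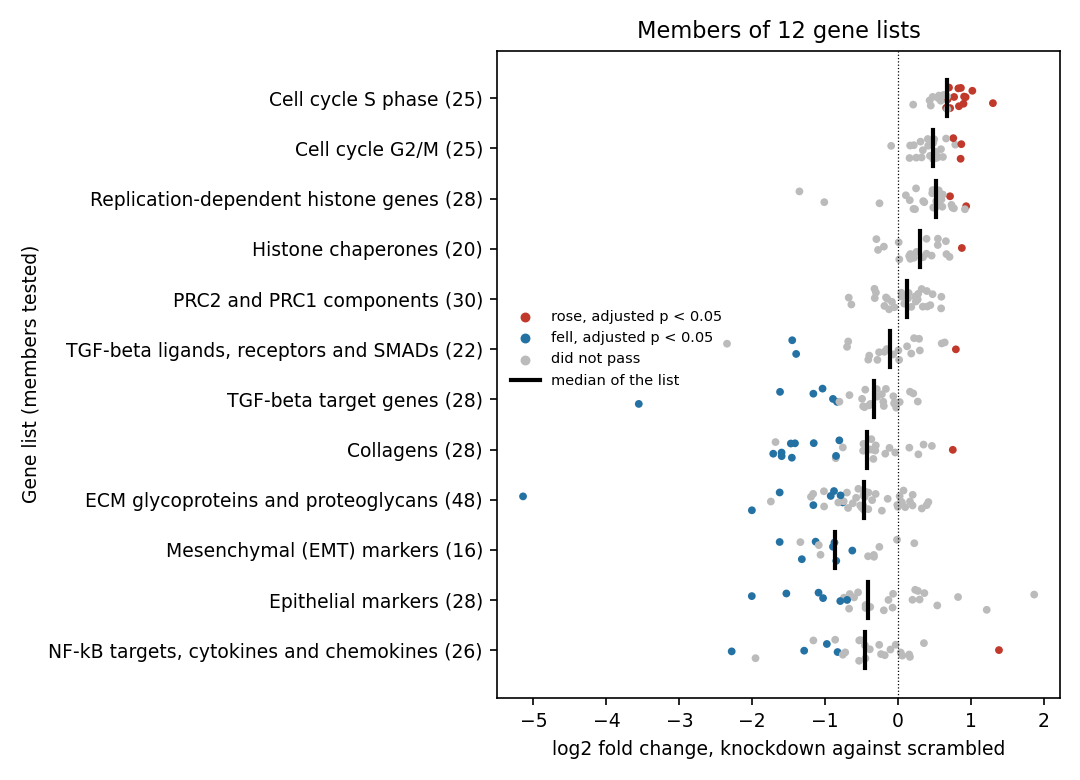
Log2 fold change of knockdown against scrambled cells (horizontal axis) for the tested members of 12 gene lists (vertical axis, number tested in brackets). Red and blue points rose or fell at an adjusted p under 0.05, grey points did not pass, vertical spread within a list has no meaning and black bars are medians; the medians run from 0.67 for the S phase list to -0.86 for the mesenchymal markers.

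No gene of the Polycomb list passed in the main fit. EZH2 stood at 10.5 ± 1.44 CPM in scrambled and 15.9 ± 0.26 CPM in knockdown cells (SD, n = 2 each). Its log2 fold change was 0.59 ± 0.15 (SE) with an adjusted p of 0.0695. In edgeR with the GC correction it was 0.52 with an adjusted p of 0.00377, and with 8 samples the adjusted p was 0.000503. EZH2 passed without scrambled library 1 or 2 (adjusted p = 0.000249 and 0.00884) and in 5 of 18 alternatives in all, with adjusted p-values from 0.000249 to 0.659. The PRC2 and PRC1 list also holds histone demethylases of the KDM6 family, which are part of neither complex. Of its 30 tested genes none passed in the main edgeR fit, over all genes or adjusted over the list alone, while 8 had an unadjusted p under 0.05. In edgeR 10 rose and 2 fell with 8 samples, and 6 rose and 1 fell with the GC correction. DESeq2 called 3 of the genes, 2 up and 1 down, and limma-voom 0. Without scrambled libraries 1 and 2, 11 and 8 rose and 6 and 2 fell. The camera adjusted p was 0.163 (range over 13 alternatives 0.0477 to 0.391, the lowest from fry, which tests for movement of the list itself and not against other genes). MTF2 had an adjusted p of 0.102, with a log2 fold change of 0.59 ± 0.17. The abundant members RBBP7, RBBP4 and PHC2 had log2 fold changes of 0.34 ± 0.12, 0.32 ± 0.15 and -0.19 ± 0.14. Of 66 developmental regulators that PRC2 represses in many cell types, 31 were found among the rows and 27 were tested. Members without enough counts are therefore not covered. Of the 27 none passed in the main edgeR fit, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. In edgeR 3 of the 27 fell with 8 samples and 2 fell with the GC correction, and none rose in either fit. DESeq2 and limma-voom called 0 of them, and without scrambled library 1, 1 rose and 4 fell, and without knockdown library 2, 1 fell. The camera adjusted p was 0.145 (range over 13 alternatives 0.0229 to 0.527). SOX9 and GATA6, among the most abundant of those regulators, had log2 fold changes of -0.07 ± 0.14 and -0.27 ± 0.14.

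Cell cycle genes were higher in the knockdown. Of 25 S phase genes tested, 13 rose, none fell and 12 did not pass (24 rose adjusted over the list alone), with a median log2 fold change of 0.67. Besides CCNE2, the replication factor CDC45 rose 1.90-fold, the helicase subunit MCM6 1.86-fold from 15.1 ± 1.43 to 28.04 ± 1.62 CPM (SD, n = 2 each), and the transcription factor E2F1 1.82-fold. Their adjusted p-values were 0.0187, 0.0207 and 0.0207. Of 25 G2/M genes, the kinase CDK1, the mitotic kinesin KIF11 and the spindle protein NUSAP1 rose 1.81-, 1.82- and 1.69-fold, and 22 did not pass (16 rose adjusted over the list alone). TOP2A, with 121.2 ± 21.7 and 191.3 ± 6.51 CPM, had an adjusted p of 0.0572. The camera adjusted p was 3.93e-14 for the S phase and 4.12e-08 for the G2/M list (adjusted p = 0.316 with an estimated correlation for both). The lowest of 13 alternatives was 1.13e-15 and 1.21e-09. Without knockdown library 1 or 2, 1 and 2 S phase genes and no G2/M gene rose. Without scrambled library 1 or 2, 23 and 24 S phase genes and 20 and 17 G2/M genes rose.

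Histone genes and chaperones followed the cell cycle genes in direction. Of 28 replication-dependent histone genes, HIST1H2AI (now H2AC13) rose 1.91-fold, HIST1H2AB (now H2AC4) rose 1.64-fold, and 26 did not pass (9 rose adjusted over the list alone). The median log2 fold change of the list was 0.52. Histone genes are near-identical copies, so the counts of single members are uncertain. Of 20 histone chaperones and assembly factors, CHAF1B, a subunit of chromatin assembly factor 1, rose 1.83-fold from 6.84 ± 0.91 to 12.54 ± 0.54 CPM (SD, n = 2 each), and 19 did not pass (7 rose adjusted over the list alone). ASF1B, MCM2 and HJURP had adjusted p-values of 0.0506, 0.0611 and 0.0614. The camera adjusted p was 8.88e-05 for the histones (adjusted p = 0.400 with an estimated correlation; lowest of 13 alternatives 4.12e-07). It was 0.00154 for the chaperones (adjusted p = 0.316 with an estimated correlation; lowest 0.000538). Without knockdown libraries 1 and 2, none and 2 histone genes and no chaperone rose. Without scrambled libraries 1 and 2, 10 and 16 histone genes and 13 and 8 chaperones rose, and 1 chaperone fell in each case.

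Of 15 UBR ligases and enzymes of H2B ubiquitination tested, UBR7 fell, the deubiquitinase USP44 rose and 13 did not pass (1 fell and 1 rose adjusted over the list alone). The list, UBR7 included, had a camera adjusted p of 0.327, and its other members were not tested as a group. The call of USP44 did not hold without knockdown library 1 or 2, and its fold change in those fits is not reported here. The median log2 fold change of the list was 0.06, and 0.13 without scrambled library 1. UBR4 and WAC had log2 fold changes of 0.07 ± 0.12 and -0.08 ± 0.15 (SE).

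The scrambled libraries differed from each other by more than the knockdown libraries did, along the GC content of the transcripts. Over 11518 genes with a mean above 1 CPM and known GC content, the SD of the log2 ratio was 0.36 between the scrambled and 0.16 between the knockdown libraries. Scrambled library 1 exceeded library 2 by a median of 0.35 in log2 units among genes with up to 42.3% GC, and the median difference was -0.40 among genes with at least 58.6% GC. Across genes, which are not independent replicates, Spearman's rho with GC content was -0.80 between the scrambled libraries, 0.25 between the knockdown libraries and -0.34 for knockdown against scrambled. A correction for GC content, chosen after seeing the data, gave 3028 changed genes, 1354 up and 1674 down, and all 617 genes were among them.

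**Figure D4:**
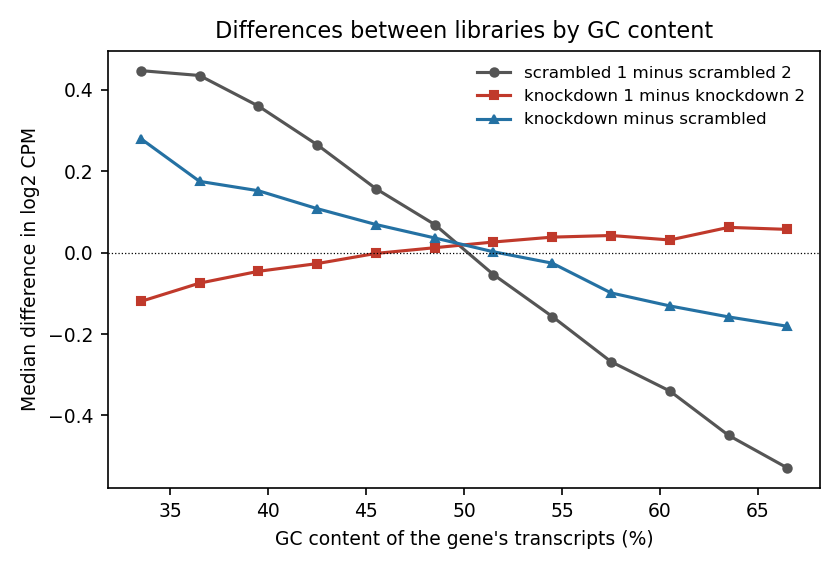
Median difference in log2 CPM (vertical axis) of genes grouped by the GC content of their transcripts in percent (horizontal axis). Scrambled library 1 minus library 2 (grey) runs from 0.45 at low to -0.53 at high GC content, knockdown library 1 minus library 2 (red) from -0.12 to 0.06, and knockdown minus scrambled (blue) from 0.28 to -0.18.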

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

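The 24 rows with a date in place of a symbol lie outside the comparisons, and their test was chosen only after the data were seen. With these rows kept, 1 of 24 passed the threshold of edgeR's test. Its log2 fold change was 1.62 ± 0.20 (SE), from 0.72 and 0.71 CPM in the scrambled libraries to 2.09 and 2.29 CPM in the knockdown libraries (adjusted p = 0.0105). Both knockdown libraries were above both scrambled libraries. The gene behind the row was not analysed here, and no biological explanation was tested.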

How the results depend on the processing

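The GC-corrected fits, the fits without 12 abundant rows, the fits with date rows and the list tests on 8 samples were added after seeing the data. With scaling by library size alone 11 genes passed (6 up, 5 down), all of them at least 2-fold, while 29 of 33 lists kept direction and call. UBR7 lost its call at a log2 fold change of -0.95 (adjusted p = 0.659; range over 18 alternatives 4.56e-14 to 0.659), and HLA-B, which fell, stood at 0.036. Ribosomal RNA shares between 25.6% and 57.3% enter those library sizes. In the other 17 alternatives UBR7 passed, at -1.50 to -1.78. Counts of changed genes, against 617, were 1296 with DESeq2, 4640 with 8 samples, 3028 with the GC correction and 223 to 5986 with 1 library left out, where the lone library is assumed to vary like the others; the cause was not tested. Counts of at least 2-fold, against 327, were 548, 507 and 223 to 906 in the last 3 cases, and 68 (6 up, 62 down) when tested against 1.5-fold. Without knockdown library 1 or 2, 179 and 204 of the 617 genes passed. The 24 largest changes all passed in 16 of 18 alternatives, 23 (not CD83) without knockdown library 2 and 0 with library size alone.

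The replicate numbers come with no shared day or culture in the labels, so they were not taken to pair the samples. Deviations of same-numbered libraries correlated at -0.31 across genes and those of crossed libraries at 0.31. With 2 libraries per group these values mirror each other, so they cannot decide how the libraries pair. With the replicate block 1079 genes passed, 501 of them at least 2-fold.

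Of 22 lists that passed, 0 passed with an estimated correlation and 14 lost their call with fry. Over all 33 lists, 10 passed with fry, some of them not among the 22. The estimated correlation gave an adjusted p of 0.316 for the S phase, G2/M, collagen, glycoprotein, mesenchymal and TGF-beta target lists and 0.400 for the histones. That form of camera had little power with 2 residual degrees of freedom, so these losses do not decide whether the lists moved. For the histone, G2/M, TGF-beta target and S phase lists the estimated correlation also lay above the preset and may add to the loss. With fry, which tests whether a list moves on balance one way and not against other genes, the G2/M and TGF-beta target lists stood at 0.0547 and the histones at 0.191. In the remaining alternatives these 7 lists passed. For the 149 named genes besides UBR7, 2303 of 2660 alternative values kept their direction and side of the threshold, 155 lost and 200 gained a call, and 2 reversed. The reversal of HLA-B, above, came with the shift of all genes by 0.66 (median) under library size alone and says nothing about that gene. The other was EGFL7, at -0.002, which stood at 0.374 without scrambled library 2 (adjusted p = 0.0200) and at -0.307 without scrambled library 1 (adjusted p = 0.0199; range over 18 alternatives 0.0199 to 0.9998); the cause was not tested. Genes under 0.3 CPM had a median SE of 0.48, so only larger changes could pass there.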

Other observations

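Lists of inflammatory and immune genes tended downward in the knockdown, though most members did not pass and some rose. Of 26 NF-kB targets, cytokines and chemokines, IL6, SOD2, IL1B and CSF2 fell, the inhibitor of apoptosis BIRC3 rose and 21 did not pass (11 fell and 1 rose adjusted over the list alone). SOD2, the mitochondrial superoxide dismutase, fell 2.44-fold from 125.3 ± 6.58 to 51.3 ± 3.53 CPM (SD, n = 2 each; adjusted p = 0.00522), and IL1B, interleukin 1 beta, fell 1.97-fold. Of 32 interferon-stimulated genes, IFIT2, OASL, DDX60 and IFIT3 fell 2.15-, 3.02-, 2.08- and 1.82-fold, USP18, a negative regulator of interferon signalling, rose from 0.48 to 1.10 CPM, and 27 did not pass (10 fell and 2 rose adjusted over the list alone). Of 18 antigen presentation genes, B2M, PSMB9 and HLA-B fell 1.59-, 1.63- and 1.52-fold and 15 did not pass (7 fell and 1 rose adjusted over the list alone). HLA genes are close copies, and their counts are uncertain, as are those of SOD2, IFIT2 and IFIT3, which overlap other rows of the table. Camera adjusted p-values of the 3 lists were 0.000156, 0.00469 and 0.00187 (adjusted p = 0.316, 0.316 and 0.397 with an estimated correlation). The lists passed in 11, 12 and 11 of 13 alternatives, with lowest values of 2.76e-05, 0.000231 and 0.000591. Without knockdown library 1, 2, 2 and 0 members of these lists fell, and without knockdown library 2, 3, 2 and 0 fell; in both cases 1, 0 and 0 rose, so the call of USP18 did not hold. Without scrambled library 1, 11, 14 and 13 fell and 1, 3 and 1 rose, and without scrambled library 2, 11, 14 and 8 fell and 2, 4 and 2 rose.

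None of 39 ribosomal protein genes passed in the main edgeR fit, over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05. DESeq2 called 2 falls and limma-voom 0, while edgeR called 21 falls with 8 samples and 11 with the GC correction. Of the 39 genes, 38 had negative log2 fold changes, and the median was -0.21. The camera adjusted p was 0.000171 (adjusted p = 0.400 with an estimated correlation, lowest of 13 alternatives 8.77e-07). Without scrambled libraries 1 and 2, 27 and 9 of them fell. Of 16 luminal epithelial markers, MUC1, KRT19 and KRT8 fell and 13 did not pass (7 fell adjusted over the list alone). The camera adjusted p was 0.000498 (adjusted p = 0.316 with an estimated correlation, lowest 2.50e-05). KRT19 and KRT8 are also on the epithelial list above. Of 35 WNT genes, WNT10A, the WNT inhibitor DKK1, the ligase RNF43 and the receptor LGR4 fell and 31 did not pass (5 fell adjusted over the list alone). Of 20 YAP/TAZ targets, F3, tissue factor, fell 1.86-fold from 299.6 ± 34.3 to 160.7 ± 7.38 CPM (SD, n = 2 each) and 19 did not pass (4 fell adjusted over the list alone). Of 5 haematopoietic markers CD14 fell and 4 did not pass (1 fell adjusted over the list alone). The WNT, YAP/TAZ and haematopoietic lists had camera adjusted p-values of 0.0332, 0.0280 and 0.0181 (adjusted p = 0.316 with an estimated correlation for each). They passed in 6 of 13, 8 of 13 and 6 of 11 alternatives, with lowest values of 0.0242, 0.0121 and 0.0174. CD14 did not pass without knockdown library 2 (adjusted p = 0.0573); without knockdown library 1 a haematopoietic marker rose and 1 fell, and without scrambled libraries 1 and 2, 2 and 1 fell. Without scrambled library 1, 8 luminal markers, 9 WNT genes and 9 YAP/TAZ targets fell and 0, 3 and 3 rose. Without scrambled library 2, 8, 5 and 7 fell and 1, 0 and 0 rose, and without knockdown library 1 or 2, 2, 3 and 0 fell. Lists that did not pass in camera were endothelial markers (adjusted p = 0.107; KDR rose), the unfolded protein response (0.0508; DDIT3 fell), BMP signalling (0.681; BMP4 and FST fell) and p53 targets (0.450; PHLDA3 fell). Adjusted over the list alone, 1 endothelial marker and 1 BMP gene rose, and 3, 1, 4 and 3 members of these lists fell. Of their members 1, 1, 3 and 8 rose and 4, 11, 4 and 7 fell without scrambled library 1, and 2, 1, 2 and 3 rose and 1, 8, 4 and 5 fell without scrambled library 2. Leaving out knockdown library 1 gave 1 fall among p53 targets and no other call in these 4 lists, and leaving out knockdown library 2 gave none. Heat shock and immediate-early genes (0.0756), hypoxia and glycolysis (0.602) and cholesterol synthesis (0.691) had no member past the threshold in the main edgeR fit. Unadjusted p was under 0.05 for 6, 9 and 4 members, DESeq2 called 1, 2 and 0, and limma-voom 0. In edgeR with 8 samples 0, 6 and 3 rose and 9, 4 and 5 fell. With the GC correction 0, 7 and 3 rose and 4, 3 and 5 fell. Adjusted over the list alone in the main fit, 0, 2 and 0 members of these lists fell. Their rises were 0, 4 and 3 and their falls 10, 10 and 7 without scrambled library 1, and without scrambled library 2, 0, 9 and 4 rose and 6, 3 and 4 fell. Among their most abundant members, ENO1, LDHA, HSPA8 and INSIG1 had log2 fold changes of -0.05 ± 0.15, 0.05 ± 0.12, -0.15 ± 0.13 and -0.31 ± 0.12 (SE).

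The tests of counting noise, of other splits of the libraries, of smooth muscle genes and of EZH2 were chosen only after the result was seen. The lower matrix, mesenchymal and TGF-beta target genes, 116 genes of which 27 fell and 1 rose, had a median log2 fold change of -0.46 (95% bootstrap interval -0.52 to -0.36). This and the bootstrap intervals below were taken over genes of the same 4 libraries, so they do not measure the spread between libraries. With the GC correction the median was -0.39 (-0.52 to -0.27), which argues against the GC trend as the whole cause. Under 5 scalings the median stayed at least 0.44 below that of all genes (nearest value -0.44), but a scaling moves every gene of a library alike, so this test could not have come out otherwise and a change in total RNA per cell stays open. Stromal cells in the scrambled cultures cannot be told apart from a change within the cells: the summed fall of COL1A1, COL1A2, COL3A1, DCN and LUM was 0.216 of the fall of FN1, between the limits of 0.1 and 1 set beforehand. The falls of the smooth muscle genes MYH11, DES and ACTG2, all from low levels, go with cells of another type, while ACTA2 did not pass, and they do not decide it. An effect of lower UBR7 on these genes, in the cancer cells themselves, may also account for the pattern.

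For the higher cell cycle and histone genes, 78 genes with a median log2 fold change of 0.55 (0.48 to 0.61), the GC correction left 0.52 (0.47 to 0.63), which argues against GC content as the whole cause. Their median stayed at least 0.55 above that of all genes under the 5 scalings, with the same limit of that test. A difference in the share of cycling cells or in growth between the cultures at harvest, and an effect of lower UBR7, stay open and were not tested.

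The spread between the scrambled libraries was wider than between the knockdown libraries. Their chi-square per degree of freedom was 18.6 times the highest value of samples sharing a stem, but this sets separate libraries against counting noise, which the knockdown libraries also exceeded (4.31 to 4.56 against at most 1.27), and decides nothing about the wider spread. The GC correction lowered the ratio of SDs between scrambled and knockdown libraries from 2.32 to 1.54 (95% bootstrap interval 1.46 to 1.63), against limits of 1.2 and 1.5 set beforehand. GC content may therefore account for part of the spread, and whether it leaves a further difference beyond the limit cannot be told apart with these values. No biological explanation was tested for differences within a group.

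Of the 3 splits of the 4 libraries into 2 and 2, only 1, the real one, gave 617 genes or more, and the highest other split gave 0 in edgeR (51 and 193 genes at an unadjusted p under 0.05). With 3 splits no share under 0.05 can be reached. As a hypothesis, EZH2 may follow the cell cycle genes, since its log2 fold change of 0.59 lay at percentile 28 of the S phase list (10th to 90th percentile 0.46 to 0.92). Of the 10 nearest tested protein-coding genes on chromosome 14, ITPK1 fell too (log2 fold change -0.68, edgeR adjusted p = 0.0358) and 9 did not pass. Their median log2 fold change was 0.06, inside the central 95% (-0.34 to 0.28) of 10000 random runs of neighbouring genes.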
